A study of Mus musculus with 24 samples.

How the data were processed

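Total RNA was purified with the ReliaPrep RNA Cell Miniprep System (Promega) and turned into biotin-labelled cRNA with the Illumina TotalPrep kit (Life Technologies), per the labels' protocols. GenomeStudio made the values, per the submitters' processing notes, and its version is not given in the sources used here. The values used were the deposited probe intensity table on a linear scale, with 25697 probes on each of 24 arrays. Judged from the values, the deposited intensities were background-subtracted (45.4% to 54.7% of probes per array lay under 0) and already scaled between arrays, since every array had a mean of 693. A second deposited table with signals and detection p-values was not used, because its 48 columns match no sample label. The planned correction by detection p was therefore replaced by the fallback set beforehand (normexp, then quantile), and the planned filter by one chosen later.

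Groups came from the labels: 12 groups of 2 arrays, and 0 unassigned samples. Comparisons, gene lists, thresholds, the rule for named genes and the alternatives were fixed before the data were examined, except where stated.

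Intensities were corrected with limma's normexp (offset 50), quantile normalized and put on the log2 scale. As the arrays carried no detection value, an array's background spread was the root mean square of its values under 0. A probe counted as above background over 1.645 times this spread, and probes above it on both arrays of at least 1 group were kept (10114, of which 9506 had a gene name). This filter, chosen after the tables were seen, replaced detection p. Of all probes 23978 carried 1 gene symbol and 1719 none. Symbols were looked up by gene ID for 23962 probes and the platform's symbol was kept for 16. The brightest passing probe stood for each gene, leaving 7693 of 16593 genes. For 1457 genes several probes passed.

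A limma model with 12 group means was fitted to all 24 arrays, giving 12 residual degrees of freedom and 6.34 prior ones, followed by moderated tests. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change. The comparisons, 15 in all, were each KOSM day, iPSC and fKOSM at 0 nM against MEF, each Shield1 dose against 0 nM at day 22, the days at 0 nM, the move to 100 nM, both 100 nM groups against iPSC, a dose trend and the difference between early and late responses. The trend used weights -3, -1, 1 and 3 on the 4 doses and called slopes of at least 0.333 log2 per step. The position of an array was its projection on the MEF to iPSC difference.

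Gene lists, 27 with 596 members (535 on the array), covered vector factors, the pluripotency network, earlier, later and formative pluripotency genes, epithelial, fibroblast, epidermal, interferon, antigen presentation, cell cycle, p53, germline, endoderm, mesoderm, neural, trophoblast, glycolysis, oxidative phosphorylation, DNA methylation, imprinted, TGF-beta and BMP, macrophage, endothelial, muscle and adipose, sex-linked and immediate early genes. The 23 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with the correlation estimated. Of 345 list tests 135 had an adjusted p under 0.05 with the preset value, and 94 of these with the estimated one. Smaller lists are given gene by gene. Named genes were the 8 largest rises and falls whose groups did not overlap, up to 4 called members per list with the largest changes, and a fixed set of pluripotency, fibroblast and epithelial genes.

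The methods were tested on simulated data. For 100 against 0 nM (7672 genes), 34 of 50 genes changed 4-fold and 37 of 47 changed 8-fold were called, against 2 of 49 changed 2-fold, with 16 unchanged genes called. Estimates were compressed, with medians of 0.73, 1.45 and 2.11 log2 for true changes of 1, 2 and 3. At 4-fold and 8-fold the trend (7644 genes) found 30 of 46 and 32 of 47, with 6 unchanged genes called. Early against late (7667 genes) found 8 of 48 and 27 of 49, with 4. In each of these tests the false share of calls was above the adjusted p threshold. The list test (7601 genes) called 3 of 3 shifted lists and 1 of 17 unshifted ones.

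Alternatives were cyclic loess and median scaling, no filter, no minimum fold, a fit of the compared groups alone, replicate number as a block, array weights, the mean of a gene's probes, a trended and robust variance, and leaving out each array. A floor of 50 in place of normexp, a background multiple of 2.326, background spread as a covariate and leaving out the 2 dimmest arrays were chosen after seeing the data. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.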

Results

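The series measured mouse gene expression on 24 Illumina bead arrays, which read labelled RNA as the brightness of gene-specific probes, in 12 groups of 2 arrays. Mouse embryonic fibroblasts (MEF, labelled as somatic cells at day 0 of infection) were compared with cells sampled 4, 8, 19 and 33 days after infection with a vector named KOSM. From background knowledge, such a vector expresses Klf4, Oct4 (gene Pou5f1), Sox2 and c-Myc, the factors that turn fibroblasts into induced pluripotent stem cells (iPSC). A second vector, fKOSM, was used with Shield1, a small molecule that protects a protein carrying a destabilising domain from degradation; from knowledge of the study, Klf4 carried it. The fKOSM cells had 0, 10, 30 or 100 nM Shield1 and were sampled at day 22, or had 0 nM until day 79, or were moved from 0 to 100 nM at day 25 and sampled at day 79. An iPSC clone completed the set. Its title, Mn/KOSM#24, names it for KOSM, while its vector infection and Shield1 entries read none, so it is not known to be free of vector. No group had Shield1 without fKOSM. MEF were sampled only at day 0, and no group had a mock infection or an empty vector. Against MEF, effects of the factors therefore cannot be told apart from those of infection or time in culture.

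The background spread per array was 80.7 to 303 intensity units (median 116), and 25.1% to 36.8% of probes lay above background on an array (median 33%). The dimmest arrays were replicate 1 of KOSM day 33 (background spread 303) and replicate 2 of fKOSM at 0 nM, day 22 (191). The 2 arrays of a group correlated across genes with r between 0.937 for KOSM day 33 and 0.976 for KOSM day 8. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical, and the number of arrays limits the precision. All changes are log2 differences between group means of 2 arrays each, ± the standard error of the limma fit, with 7693 genes tested. "Higher", "lower", "rose" and "fell" are used for genes with an adjusted p under 0.05 and at least a 2-fold change. Where a gene lay above background on neither array of the dimmer group, the fold is given as "at least", computed against that group's background limit or its own value if higher. Such a gene's log2 difference includes a value in the noise. The brightest probes also bunched at the top of the scale, with 6 to 31 probes per array (median 14) within 10% of the brightest. Among named genes Igf2, Acta2 and Serpinf1 in MEF and Dppa5a in iPSC lay at 80% or more of the brightest on both arrays, and their folds against these groups are given as "at least" too. By simulation, printed differences and folds are compressed, and false calls can exceed the adjusted p threshold. For gene lists, camera compared members with all other genes, with adjusted p at the preset correlation unless stated. With an estimated one it could be far larger: 2.28e-05 against 2.02e-23 for fibroblast genes at day 19. For interferon genes at day 4 it was 0.00714 against 1.92e-07. Unless stated, counts adjusted over the list alone equalled those given, and an adjusted p under 0.05 stayed so with an estimated correlation. The median change over all genes exceeded 0.1 against MEF at day 8 (0.11), day 19 (0.11), day 33 (0.18) and in fKOSM cells at 0 nM (0.12).

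The first question was how far each population had moved from MEF towards iPSC. Over the 1876 genes that differed between MEF and iPSC, with MEF at 0% and iPSC at 100%, KOSM cells lay at 25.5% ± 0.77 (SD, n = 2 arrays) at day 4, 52.1% ± 0.54 at day 8, 76.6% ± 0.9 at day 19 and 80.1% ± 1.53 at day 33. At day 22 fKOSM cells lay at 67.6% ± 2.57 with 0 nM, 70.6% ± 2.95 with 10 nM, 78.8% ± 0.29 with 30 nM and 84.2% ± 1.4 with 100 nM. At day 79 they lay at 68.6% ± 2.5 with 0 nM throughout and at 81.2% ± 0.58 after the move to 100 nM. In each infected group the 868 genes lower in iPSC placed the cells farther along than the 1008 higher genes. In fKOSM cells at day 22 these parts were 80.1% ± 6.48 and 54.6% ± 1.5 with 0 nM, 73.1% ± 4.48 and 68% ± 1.36 with 10 nM, 83.9% ± 1.57 and 73.6% ± 2.21 with 30 nM, and 93.1% ± 3.86 and 74.9% ± 1.16 with 100 nM. They were 83.5% ± 3.07 and 69.3% ± 5.04 at KOSM day 19. At day 33 they were 92.3% ± 8.61 and 67.5% ± 12.1, a spread the overall SD of 1.53 hides. At KOSM day 4 (27.3% ± 5.9 and 23.6% ± 4.56) the gap was under the SD of either part. This projection had no test. The first 2 principal components held 40.9% and 13.6% of the variance.

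**Figure D1:**
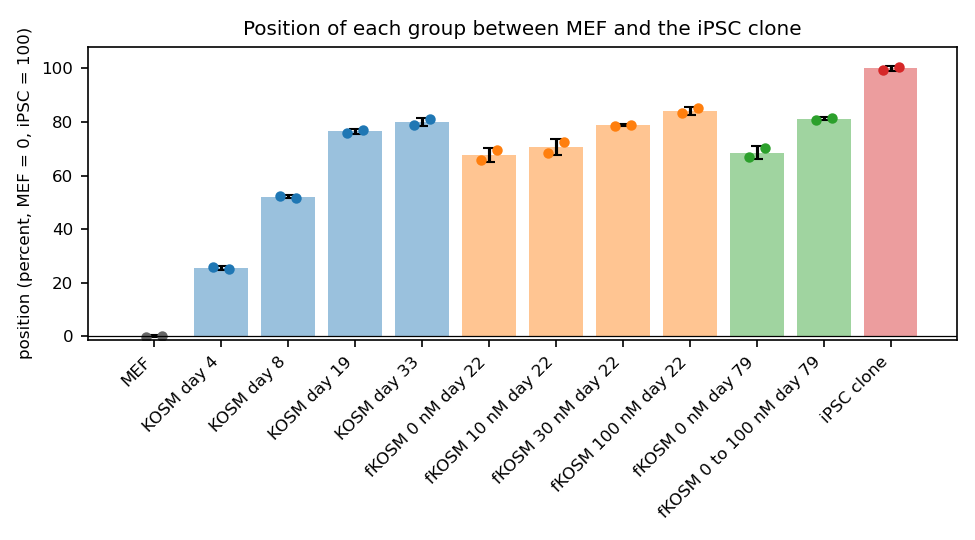
Position of each group between MEF (0) and the iPSC clone (100), in percent of the mean difference over 1876 genes, with bars for group means, dots for the 2 arrays and error bars for the SD. KOSM cells moved from 25.5 at day 4 to 80.1 at day 33, and fKOSM cells at day 22 from 67.6 with 0 nM Shield1 to 84.2 with 100 nM.

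KOSM cells at day 4 against MEF addressed which genes had changed first after infection. Sox2 (6.15 ± 0.26, at least 23.8-fold, adjusted p = 3.16e-11), the vector factor, was the largest rise, from 7.40 ± 0.54 (SD, n = 2) in MEF to 13.54 ± 0.13. The Sox2 probe stayed above its iPSC level in every infected group, and these arrays do not separate vector transcript from the cell's own. Acsl6 (4.35 ± 0.20, at least 5.38-fold, adjusted p = 8.76e-11), an acyl-CoA synthetase whose second probe averaged 8.10 in MEF and 8.64 at day 4, and the nuclear pore gene Nup210 (3.49 ± 0.30, at least 4.94-fold) rose as well, with the globin Hba-a1 (3.80, at least 3.53-fold), Popdc3 (3.30, at least 5.08-fold), Nudt11 (3.08, at least 5.97-fold) and the imprinted gene Phlda2 (2.96, at least 2.67-fold). The adipokine-related C1qtnf3 (-3.96 ± 0.32, 15.6-fold, adjusted p = 2.27e-07) was the largest fall, with Ccn2 (-2.66 ± 0.38, 6.32-fold), the matrix genes Mfap5 (-2.50) and Eln (-2.35), Rnd3 (-2.65), Igfbp3 (-2.64), Ctsk (-2.36) and Prelp (-2.33). Of the other vector factors, neither Pou5f1 (-0.63, adjusted p = 0.167) nor Klf4 (-0.28, adjusted p = 0.583) was called.

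Among 18 interferon and antiviral genes measured at day 4, 7 were higher, 0 lower and 11 not called (median 0.65, adjusted p = 1.92e-07). The higher members included Isg15 (2.74 ± 0.34, 6.66-fold, adjusted p = 3.58e-05), Ifit3 (2.59 ± 0.35, 6.03-fold), Parp14 (1.66) and Rsad2 (1.59). The 2 MEF arrays lay apart on several of these genes, with an SD of 1.07 for Isg15 and 1.05 for Ifit3 in MEF, against 0.11 and 0.05 at day 4. Of 28 fibroblast and mesenchymal genes, 0 were higher, 5 lower and 23 not called (median -0.61, adjusted p = 2.35e-06), while Thy1 (-0.64, adjusted p = 0.293), Col1a1 (0.03, adjusted p = 0.964) and Vim (-0.63, adjusted p = 0.246) were not called. Of 27 cell cycle genes, 6 were higher, 0 lower and 21 not called (median 0.46, adjusted p = 0.000119), Aurka (1.77) and Mcm5 (1.71) among the higher, and the proliferation factor Mybl2 (2.10) rose with them. The TGF-beta and BMP responses gave 0 higher, 2 lower and 11 not called (median -0.43, 0 higher and 3 lower adjusted over the list alone, adjusted p = 0.000222), with Inhba (-1.58) lower. Trophoblast genes gave 2 higher, 0 lower and 6 not called (median 0.28, adjusted p = 0.00817), namely Phlda2 (2.96) and Tfap2c (1.27). Glycolysis genes gave 1 higher, 1 lower and 16 not called (adjusted p = 0.0166, and 0.0866 with an estimated correlation). Oxidative phosphorylation gave 1 higher, 0 lower and 24 not called (adjusted p = 0.036, and 0.382 with an estimated correlation). Immediate early and stress genes gave 0 higher, 2 lower and 11 not called (0 higher and 3 lower adjusted over the list alone, adjusted p = 0.0212, and adjusted p = 0.0866 with an estimated correlation), with Trib3 (-1.24) lower. DNA methylation and Polycomb genes gave 2 higher, 0 lower and 11 not called (adjusted p = 0.0516), Dnmt3b (1.49) and Cbx2 (1.24) being higher, and the pluripotency network 1 higher, 1 lower and 25 not called (adjusted p = 0.462). Nanog (-0.06, adjusted p = 0.919), Esrrb (-0.53, adjusted p = 0.147), Cdh1 (-0.32, adjusted p = 0.717) and Krt8 (0.04, adjusted p = 0.968) were not called. Limma called 445 genes, 237 higher and 208 lower. Cyclic loess scaling gave 158 higher and 236 lower, median scaling 210 and 95, and without replicate 1 of KOSM day 4 the total was 292.

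By day 8, Sox2 (6.77 ± 0.26, at least 36.7-fold, adjusted p = 1.87e-12) and Acsl6 (6.44 ± 0.20, at least 23-fold, adjusted p = 1.55e-13) were the largest rises against MEF. Avil (5.08 ± 0.34, at least 12.3-fold), the amino acid transporter Slc38a5 (4.87, at least 4.49-fold), Gldc (4.82, at least 16.6-fold) of glycine cleavage, Nup210 (4.86, at least 12.9-fold), Nudt11 (4.66, at least 17.8-fold) and the trophoblast factor Tfap2c (4.14, at least 6.87-fold) followed. The pluripotency factors Esrrb (2.83 ± 0.22, at least 3.03-fold, adjusted p = 2.01e-08) and Pou5f1 (1.93 ± 0.26, at least 2.35-fold, adjusted p = 1.87e-05) were higher, while Nanog (0.67, adjusted p = 0.0557) and Dppa4 (0.93, under 2-fold, adjusted p = 0.0016) were not called. C1qtnf3 (-4.58 ± 0.32, at least 14.9-fold), the secreted matrix-associated Ccdc80 (-4.54, at least 3.56-fold), Gpnmb (-3.60, at least 9.3-fold), Eln (-3.56), Slit2 (-3.34, 10.1-fold), Mmp14 (-3.25, 9.48-fold) and the imprinted growth inhibitor Cdkn1c (-3.56, 11.8-fold) were among the largest falls.

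Of 28 fibroblast genes at day 8, 0 were higher, 23 lower and 5 not called (median -1.72, adjusted p = 2.02e-16), with Lox (-2.98 ± 0.29, 7.91-fold), Col1a1 (-1.71), Vim (-1.66) and Thy1 (-1.64) lower. Cell cycle genes gave 11 higher, 0 lower and 16 not called (median 0.89, adjusted p = 6.48e-06), Aurka (2.67, 6.34-fold), Mcm5 (2.22) and Cdk1 (2.20) among the higher. TGF-beta and BMP responses gave 0 higher, 5 lower and 8 not called (median -0.73, adjusted p = 0.000225), and Ccn2 (-3.23, 9.36-fold) was lower. Of 27 genes of the pluripotency network, 3 were higher, 1 lower and 23 not called (adjusted p = 0.0422, and adjusted p = 0.0612 with an estimated correlation), with Mybl2 (2.99), Esrrb (2.83) and Zfp296 (2.83) higher. Of 11 epidermal and keratinocyte genes, which mark skin epithelium, 3 were higher, 0 lower and 8 not called (adjusted p = 0.0205, and adjusted p = 0.0612 with an estimated correlation). The higher members were Krt6b (2.18), Krt17 (2.03) and Pkp1 (1.96). Immediate early genes gave 0 higher, 5 lower and 8 not called (adjusted p = 0.0064, and adjusted p = 0.0579 with an estimated correlation), with Ddit3 (-2.49) and Egr1 (-2.01) lower. Imprinted genes gave 2 higher, 7 lower and 6 not called (adjusted p = 0.0498, and 0.0779 with an estimated correlation). DNA methylation genes gave 3 higher, 0 lower and 10 not called (adjusted p = 0.0205, and adjusted p = 0.0579 with an estimated correlation), with Dnmt3b (1.87) higher. The glucose transporter Slc2a3 (2.42) and hexokinase Hk2 (2.30) rose within a glycolysis list that gave 2 higher, 2 lower and 14 not called (adjusted p = 0.474). The interferon list had 0 higher, 2 lower and 16 not called (median 0.00, mean -0.19 and test direction down, adjusted p = 0.515), with Isg15 (0.47, adjusted p = 0.372) not called. Cdh1 (0.14, adjusted p = 0.843) and Krt8 (0.94, adjusted p = 0.137) were not called. The total was 1410 genes, 648 higher and 762 lower. Cyclic loess gave 480 higher and 897 lower, with the all-gene median at 0.004.

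At day 19 epithelial, epidermal and pluripotency genes were among the highest against MEF. Ly6g6c (6.88 ± 0.30, at least 41.2-fold, adjusted p = 2.92e-12), a surface antigen, and the keratin Krt17 (6.87 ± 0.28, at least 27.9-fold) led, followed by Sox2 (6.68 ± 0.26, at least 34.4-fold), Esrrb (6.37 ± 0.22, at least 35.2-fold, adjusted p = 1.24e-13), the natriuretic peptide Nppb (6.32, at least 31.9-fold), the epithelial splicing regulator Esrp1 (6.06, at least 20-fold), Tfap2c (5.95, at least 24.1-fold) and Dppa5a (5.85, at least 30.7-fold). Pou5f1 (4.81 ± 0.26, at least 17.4-fold, adjusted p = 6.61e-11) was higher. Lox (-6.75 ± 0.29, adjusted p = 2.61e-12), a collagen crosslinker, was the largest fall, with the growth factor Ptn (-6.69, at least 55.4-fold), Svep1 (-6.27, at least 13.7-fold), Mgp (-5.94, 61.5-fold), Lpl (-5.73, at least 35-fold), Thbs2 (-5.65, 50.2-fold), C1qtnf3 (-5.46) and the chemokine Cxcl12 (-5.16, at least 23.7-fold).

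Of 28 fibroblast genes at day 19, 0 were higher, 25 lower and 3 not called (median -2.61, adjusted p = 2.02e-23), with Col5a1 (-5.12), Lum (-4.73), Col1a1 (-4.25, at least 11.4-fold), Thy1 (-3.34), Vim (-3.33) and Zeb1 (-1.94) lower. Of 27 pluripotency network genes, 17 were higher, 1 lower and 9 not called (median 1.45, adjusted p = 3.94e-10). The lower member, named after its values were seen, was Klf2 (-1.72). Earlier pluripotency genes gave 7 higher, 0 lower and 2 not called (median 1.68, adjusted p = 1.15e-05), with Gdf3 (3.5) and Fbxo15 (2.67) higher. Later ones gave 5 higher, 0 lower and 3 not called (median 2.05, adjusted p = 1.62e-05), with Zfp296 (4.33), Dppa4 (4.22, at least 4.48-fold) and Utf1 (2.66) higher. Nanog (0.46, adjusted p = 0.203) and Lin28a (0.11, adjusted p = 0.783) were not called, whereas Dnmt3l (1.45) was higher. Epidermal genes gave 9 higher, 0 lower and 2 not called (median 2.43, adjusted p = 3.33e-08), including Klk10 (4.35). Of 19 epithelial genes, 11 were higher, 0 lower and 8 not called (median 1.79, adjusted p = 9.48e-08), Cldn4 (5.30, at least 14.5-fold), Rab25 (3.74), Krt8 (3.72, at least 5.24-fold) and Cdh1 (2.22, at least 1.38-fold) rising. The cell cycle list had 13 higher, 1 lower and 13 not called (median 1.07, 14 higher and 1 lower adjusted over the list alone, adjusted p = 4.42e-05), and Mybl2 (4.60) of the network was higher. DNA methylation genes gave 6 higher, 0 lower and 7 not called (median 0.66, adjusted p = 0.00251), with Dnmt3b (3.54) higher, and formative pluripotency genes 3 higher, 0 lower and 3 not called (median 0.99, adjusted p = 0.00628), with Cldn6 (4.42) higher. Trophoblast genes gave 3 higher, 0 lower and 5 not called (median 0.28, adjusted p = 0.0065), with Phlda2 (3.79) higher. TGF-beta and BMP responses split, 2 higher, 6 lower and 5 not called (median -0.78, adjusted p = 0.00925). The imprinted list gave 3 higher, 7 lower and 5 not called (adjusted p = 0.0566), Cdkn1c (-3.88) being lower, and macrophage and blood genes 1 higher, 1 lower and 4 not called (median 0.10, mean -0.36 and test direction down, adjusted p = 0.688). The neuronal gene Stmn2 (3.53) rose. In all 1656 genes were called, 801 higher and 855 lower.

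The day 33 cells were the latest KOSM sample. Against MEF, Ly6g6c (7.20 ± 0.30, at least 51.4-fold, adjusted p = 1.12e-12), Dppa5a (7.11 ± 0.26, at least 73.3-fold), Nppb (7.11, at least 55-fold), Krt17 (6.95, at least 29.4-fold), Esrp1 (6.58, at least 28.6-fold), Esrrb (6.46, at least 37.4-fold), Sox2 (6.35, at least 27.3-fold) and the epidermal Nccrp1 (6.34, at least 37.3-fold) were the largest rises. Pou5f1 (5.21 ± 0.26, at least 22.9-fold, adjusted p = 1.94e-11), Tfap2c (5.92) and Cldn4 (5.84, at least 21-fold) rose as well. The largest falls were Lox (-7.48 ± 0.29, at least 96.3-fold, adjusted p = 3.98e-13), Ptn (-7.47, at least 50-fold), Thbs2 (-7.29, at least 92.6-fold), Mgp (-6.86, at least 57.2-fold), Svep1 (-6.27, at least 12.4-fold), Col5a1 (-5.99, 63.6-fold), the smooth muscle actin Acta2 (-5.88, at least 58.8-fold) and C1qtnf3 (-5.51). The growth factor Igf2 (-3.38, at least 10.4-fold), which is imprinted, was lower.

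The fibroblast list at day 33 had 0 higher, 25 lower and 3 not called (median -3.18, adjusted p = 1.29e-23), with Col6a1 (-5.39), Thy1 (-4.02) and Vim (-3.70) lower. The pluripotency network had 16 higher, 1 lower and 10 not called (median 1.47, adjusted p = 1.8e-10), its later genes 5 higher, 0 lower and 3 not called (median 2.85, adjusted p = 9.42e-06), and its earlier genes 7 higher, 0 lower and 2 not called (median 1.47, adjusted p = 1.55e-05). Dppa4 (5.40, at least 10.2-fold), Fbxo15 (3.81), Gdf3 (3.68), Utf1 (3.38), Dnmt3l (2.32) and Zfp42 (1.89) were higher, and Nanog (0.57, adjusted p = 0.0982) and Lin28a (0.31, adjusted p = 0.317) were not called. Epidermal genes gave 9 higher, 0 lower and 2 not called (median 2.58, adjusted p = 8.65e-08), with Krt14 (3.26) higher. Epithelial genes gave 11 higher, 0 lower and 8 not called (median 1.71, adjusted p = 1.13e-07), with Krt8 (3.39) and Cdh1 (2.05) higher. Cell cycle genes gave 13 higher, 1 lower and 13 not called (median 0.74, adjusted p = 0.000397) and formative genes 2 higher, 0 lower and 4 not called (median 0.70, adjusted p = 0.00865), Cldn6 (4.79) being higher. Interferon genes gave 0 higher, 7 lower and 11 not called (adjusted p = 0.00838, and 0.0685 with an estimated correlation), Gbp2 (-2.61) being lower. Imprinted genes gave 3 higher, 8 lower and 4 not called (adjusted p = 0.0307, and 0.0512 with an estimated correlation), Cdkn1c (-4.57) being lower. TGF-beta and BMP responses gave 2 higher, 5 lower and 6 not called (adjusted p = 0.0354, and adjusted p = 0.0574 with an estimated correlation), Id1 (2.39) being higher. The p53 target Cdkn1a (-0.73, under 2-fold, adjusted p = 0.00955) was not called. The total was 1665 genes, 707 higher and 958 lower, in the group with the dimmest array.

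The iPSC clone against MEF gave the end point of the axis. Dppa5a (7.98 ± 0.26, at least 135-fold, adjusted p = 6.23e-14), Dppa4 (7.63 ± 0.20, at least 47.5-fold), Esrrb (7.12 ± 0.22, at least 59.3-fold) and the methylation cofactor Dnmt3l (6.99 ± 0.21, at least 82.2-fold) were the largest rises, ahead of Gbx2 (5.68, at least 17.9-fold), the cell cycle factor Mybl2 (5.64, at least 16-fold), Mreg (5.63, at least 21.5-fold) and Gtsf1l (5.61, at least 11.9-fold). Pou5f1 (5.45 ± 0.26, at least 27.1-fold, adjusted p = 1.43e-11) and Nanog (3.62 ± 0.25, at least 5.31-fold, adjusted p = 1.44e-09) were higher, as were Fbxo15 (5.19, at least 9.99-fold), Utf1 (4.49, at least 11.2-fold), Zfp42 (4.23, at least 7.28-fold), Sall4 (3.35) and Alpl (1.48). The clone carried Sox2 (2.71 ± 0.26, at least 2.2-fold, adjusted p = 1.31e-07) at a level under that of every infected group. Lox (-7.69 ± 0.29, at least 117-fold, adjusted p = 2.81e-13), Ptn (-7.55, at least 60.7-fold), Thbs2 (-7.42, at least 112-fold), Mgp (-7.38, at least 69.4-fold), Svep1 (-6.42, at least 15.1-fold), Col6a1 (-6.23, 74.8-fold), Col5a1 (-5.74) and Sspn (-5.63) were the largest falls, and Thy1 (-4.11, 17.3-fold), Col1a1 (-4.65, at least 12.5-fold) and Vim (-3.63, 12.4-fold) fell with them.

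Of 27 network genes in iPSC, 22 were higher, 0 lower and 5 not called (median 3.01, adjusted p = 4.88e-20). All 9 earlier genes measured were higher, median 3.62, adjusted p = 3.21e-10. Later genes gave 7 higher, 0 lower and 1 not called (median 4.67, adjusted p = 4.44e-10), with Lin28a (0.02, adjusted p = 0.97) not called. The fibroblast list gave 0 higher, 24 lower and 4 not called (median -3.28, adjusted p = 6.15e-22) and cell cycle genes 16 higher, 2 lower and 9 not called (median 1.24, adjusted p = 1.88e-05). Epithelial genes gave 9 higher, 0 lower and 10 not called (median 0.89, adjusted p = 4.92e-05), Cdh1 (2.10) included. DNA methylation genes gave 6 higher, 0 lower and 7 not called (median 0.88, adjusted p = 0.000802), with Dnmt3b (4.96) higher, and formative genes 4 higher, 0 lower and 2 not called (median 1.5, adjusted p = 0.000644). Endoderm genes gave 4 higher, 0 lower and 5 not called (median 0.59, adjusted p = 0.00211), with Lama1 (5.51, at least 25.2-fold) and Amn (4.95) higher, and trophoblast genes 4 higher, 0 lower and 4 not called (median 0.62, adjusted p = 0.00243), with Tfap2c (5.44) higher. TGF-beta and BMP responses gave 1 higher, 4 lower and 8 not called (median -0.77, adjusted p = 0.00891), and imprinted genes 3 higher, 7 lower and 5 not called (median -0.55, adjusted p = 0.0246), with Igf2 (-3.89) lower. Germline genes gave 5 higher, 0 lower and 6 not called (adjusted p = 0.00939, and adjusted p = 0.0844 with an estimated correlation), with Tdrd12 (4.31) and Rhox5 (3.48) higher. Oxidative phosphorylation gave 5 higher, 0 lower and 20 not called (adjusted p = 0.00997, and 0.174 with an estimated correlation). P53 targets and senescence genes gave 2 higher, 3 lower and 10 not called (adjusted p = 0.458), although Cdkn1a (-2.44 ± 0.21, 5.43-fold, adjusted p = 1.88e-08) and the death receptor Fas (-1.41) fell. Antigen presentation gave 0 higher, 2 lower and 5 not called (median 0.03, mean -0.37 and test direction down, adjusted p = 0.432), with B2m (-1.84) lower. The epidermal list gave 1 higher, 0 lower and 10 not called, the higher member being Krt17 (2.12). Klf4 (0.26, adjusted p = 0.488) was not called. In all 1876 genes differed, 1008 higher and 868 lower.

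For fKOSM cells at 0 nM Shield1 and day 22, the question was how infected cells without the ligand differed from MEF. Slc38a5 (6.16, at least 11-fold), Sox2 (5.98 ± 0.26, at least 21.2-fold, adjusted p = 7.28e-12), the thyrotropin-releasing hormone precursor Trh (5.60, at least 22.6-fold), Nup210 (5.48, at least 19.7-fold), Nudt11 (5.14, at least 24.9-fold), Gldc (5.04, at least 19.4-fold), Esrp1 (4.92, at least 9.09-fold) and the placental Prl2c3 (4.69, at least 17.2-fold) were the largest rises against MEF. Pou5f1 (3.47 ± 0.26, at least 6.86-fold, adjusted p = 7.98e-09) and Dnmt3b (4.68, at least 19.6-fold) were higher, and Tfap2c (4.59, at least 9.42-fold) and Mybl2 (3.81) rose too. Igf2 (-6.72 ± 0.20, at least 105-fold, adjusted p = 2.72e-14) was among the largest falls, with Mgp (-6.64, at least 59.8-fold), Ptn (-6.43, at least 52.3-fold), Svep1 (-6.42, at least 13-fold), Lox (-6.39, 84.1-fold), Thbs2 (-6.07, 67.4-fold), C1qtnf3 (-5.50, at least 14-fold) and Scara3 (-5.02, 32.5-fold). Nanog (0.70, under 2-fold, adjusted p = 0.0412), Esrrb (0.66, under 2-fold, adjusted p = 0.0253), Dppa4 (0.63, under 2-fold, adjusted p = 0.0221), Dnmt3l (-0.53, adjusted p = 0.0632) and Zfp42 (-0.25, adjusted p = 0.663) were not called.

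Fibroblast genes at 0 nM gave 0 higher, 24 lower and 4 not called (median -2.71, adjusted p = 1.57e-23), with Col1a1 (-4.69, at least 10.8-fold), Thy1 (-3.88) and Vim (-1.78) lower. Cell cycle genes gave 16 higher, 1 lower and 10 not called (median 1.23, adjusted p = 2.57e-06), with Mcm5 (2.88) higher. Formative genes gave 3 higher, 0 lower and 3 not called (median 1.25, adjusted p = 0.000315), with Cldn6 (3.29, at least 5.84-fold) higher, and DNA methylation genes 7 higher, 0 lower and 6 not called (median 1.15, adjusted p = 0.000488). The network gave 12 higher, 1 lower and 14 not called (median 0.70, adjusted p = 0.000315), with Gdf3 (2.30) and Utf1 (1.63) higher. Epithelial genes gave 9 higher, 0 lower and 10 not called (median 0.54, adjusted p = 0.00075), with Cldn4 (2.77, at least 2.51-fold) higher. TGF-beta and BMP responses gave 1 higher, 7 lower and 5 not called (median -1.08, adjusted p = 0.000698). Interferon genes gave 0 higher, 9 lower and 9 not called (adjusted p = 0.00271, and adjusted p = 0.0552 with an estimated correlation), with Gbp2 (-2.72) and Ifit3 (-2.29) lower. Earlier pluripotency genes gave 4 higher, 0 lower and 5 not called (adjusted p = 0.0137, and adjusted p = 0.0621 with an estimated correlation), and the later ones 3 higher, 0 lower and 5 not called (adjusted p = 0.0726). Imprinted genes gave 3 higher, 5 lower and 7 not called (adjusted p = 0.0213, and 0.0512 with an estimated correlation), with Snrpn (2.49) higher. The epidermal list gave 4 higher, 0 lower and 7 not called (adjusted p = 0.0558), with Krt6b (2.87) higher. Of the mesoderm genes, Bmp4 (-4.87, at least 16.9-fold) was lower and Isl1 (1.76) higher. The total was 1526 genes, 700 higher and 826 lower.

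Shield1 at 10 nM against 0 nM at day 22 asked what the lowest dose adds. Krt17 (4.78 ± 0.28, 27.5-fold, adjusted p = 7.15e-09) was the largest rise, with the neuropeptide Npy (3.09, 8.54-fold), Xlr4a (3.04, at least 2.04-fold), Nccrp1 (2.91, 7.5-fold), Cldn11 (2.81, 7.01-fold), Atp2a3 (2.73, at least 3.74-fold), Esrrb (2.56 ± 0.22, at least 3.59-fold, adjusted p = 1.72e-06) and Fbxo15 (2.45, 5.45-fold). Dppa5a (2.30 ± 0.26, 4.93-fold, adjusted p = 4.3e-05) and Pou5f1 rose as well. Slc7a8 (-2.04 ± 0.27, at least 3.25-fold, adjusted p = 0.000173), an amino acid transporter, and Msc (-1.15, 2.22-fold) were lower.

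Of 27 network genes at 10 nM, 8 were higher, 0 lower and 19 not called (median 0.58, adjusted p = 3.51e-08), with Gdf3 (1.63), Dppa4 (1.55) and Nanog higher. Earlier genes had 4 higher, 0 lower and 5 not called (median 0.85, adjusted p = 6.2e-08) and later genes 3 higher, 0 lower and 5 not called (median 0.74, adjusted p = 0.000654). Epithelial genes gave 3 higher, 0 lower and 16 not called (median 0.54, 4 higher and 0 lower adjusted over the list alone, adjusted p = 0.000279), with Krt19 (2.01) and Cldn4 (1.33) higher, and epidermal genes 2 higher, 1 lower and 8 not called (median 0.64, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0014). The lower one was Krt6b (-1.25), whose call was lost without replicate 1 of the 10 nM group or replicate 2 of the 0 nM group. TGF-beta and BMP responses gave 2 higher, 0 lower and 11 not called (3 higher and 0 lower adjusted over the list alone, adjusted p = 0.0349, and adjusted p = 0.0662 with an estimated correlation). The imprinted Igf2 (2.13, 4.39-fold) rose. Utf1 (0.89, adjusted p = 0.246), Zfp42 (0.59, adjusted p = 0.466), Dnmt3l (0.58, adjusted p = 0.174), Cdh1 (1.17, adjusted p = 0.139) and Thy1 (0.31, adjusted p = 0.672) were not called. This was the least stable count: 177 genes were called, 167 higher and 10 lower, but 90 without replicate 2 of the 0 nM group, 105 without replicate 1 of the 10 nM group and 107 without the 2 dimmest arrays. A fit of these groups alone called 3. Median scaling moved the all-gene median from -0.04 to 0.19.

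At 30 nM against 0 nM, keratins and claudins were among the rises. Krt17 (5.03 ± 0.28, 32.7-fold, adjusted p = 2.98e-09) and Nccrp1 (4.11 ± 0.28, 17.2-fold) were among the largest, with Npy (4.22, 18.6-fold), Xlr4a (3.76, at least 3.37-fold), Ly6g6c (3.63, at least 7.76-fold), Cldn11 (3.49, 11.2-fold), Nppb (3.43, 10.7-fold), Krt19 (3.38, at least 3.34-fold) and the epidermal Krtdap (3.33, at least 2.5-fold). Pou5f1 (1.92 ± 0.26, 3.78-fold, adjusted p = 6.68e-05), Dppa5a (2.71, 6.55-fold), Esrrb (2.69, at least 3.92-fold), Fbxo15 (2.67, 6.37-fold) and Dppa4 (2.17, at least 1.52-fold) were higher. The homeobox genes Hoxb7 (-3.81, at least 3.19-fold) and Hoxc6 (-3.08, at least 4.36-fold), which keep positional identity in fibroblasts, fell with Slc7a8 (-3.59, at least 3.37-fold), Isl1 (-2.55, at least 4.25-fold), Prl2c3 (-2.52, 5.73-fold), En2 (-2.44, 5.43-fold), Reln (-2.42, at least 2.76-fold) and Avil (-2.39, 5.26-fold).

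Of 11 epidermal genes at 30 nM, 8 were higher, 0 lower and 3 not called (median 2.05, adjusted p = 4.12e-09), with Krt14 (2.78, at least 2.65-fold) and Krt16 (2.62) higher. Of 19 epithelial genes, 11 were higher, 0 lower and 8 not called (median 1.18, adjusted p = 6.59e-09), with Cldn3 (2.88, at least 2.24-fold), Cldn4 (2.46, 5.49-fold) and Krt8 (2.24, 4.73-fold) higher. The network had 8 higher, 0 lower and 19 not called (median 0.56, adjusted p = 1.66e-05), its earlier genes 3 higher, 0 lower and 6 not called (median 0.60, adjusted p = 2.66e-05), with Gdf3 (1.86) higher, and its later genes 4 higher, 0 lower and 4 not called (median 1.02, adjusted p = 0.00191). Fibroblast genes gave 0 higher, 5 lower and 23 not called (median -0.43, adjusted p = 0.0019), with Acta2 (-1.82, 3.53-fold) lower and Thy1 (-0.66, adjusted p = 0.218) not called. The BMP response gene Id1 (1.66) rose. Nanog (0.60, adjusted p = 0.155), Zfp42 (0.70, adjusted p = 0.201), Dnmt3l (0.47, adjusted p = 0.173) and Sox2 (-0.39, adjusted p = 0.337) were not called. The test called 473 genes, 394 higher and 79 lower. Median scaling gave 628 higher and 38 lower and moved the all-gene median from -0.08 to 0.19.

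Shield1 at 100 nM against 0 nM at day 22 was the full-dose comparison. Ly6g6c (5.81 ± 0.30, at least 35.2-fold, adjusted p = 1.37e-10), Krt17 (5.55 ± 0.28, 46.7-fold, adjusted p = 1.35e-10), Dppa5a (5.13 ± 0.26, 35-fold, adjusted p = 1.37e-10) and Esrrb (4.61 ± 0.22, at least 14.9-fold, adjusted p = 7.14e-11) were the largest rises, with Nccrp1 (4.63, 24.7-fold), Dppa4 (4.37, at least 6.98-fold), Nppb (4.34, 20.3-fold) and the aldehyde dehydrogenase Aldh3a1 (4.30, at least 14.4-fold). Pou5f1 (2.05 ± 0.26, 4.15-fold, adjusted p = 3.01e-05) was higher, while Nanog (0.76, adjusted p = 0.0807), Sox2 (-0.14, adjusted p = 0.841) and Klf4 (0.34, adjusted p = 0.562) were not called. Slc7a8 (-3.73 ± 0.27, at least 3.04-fold), Hoxc6 (-3.12, at least 3.94-fold), Hoxb7 (-3.07, at least 2.88-fold), Nfix (-3.03, at least 5.07-fold), Lpl (-2.72, 6.57-fold), Hoxa5 (-2.64, at least 4.87-fold), En2 (-2.54, 5.81-fold) and Gpc3 (-2.52, 5.73-fold) were the largest falls.

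Epidermal genes at 100 nM gave 8 higher, 0 lower and 3 not called (median 2.26, adjusted p = 9.78e-13), with Krt14 (3.83, at least 5.48-fold), Klk10 (3.56, at least 3.22-fold) and Krtdap (3.43, at least 2.67-fold) higher. Epithelial genes gave 9 higher, 0 lower and 10 not called (median 1.24, 11 higher and 0 lower adjusted over the list alone, adjusted p = 2.4e-12), with Krt19 (3.23, at least 3-fold), Cldn4 (2.52, 5.71-fold) and Cldn3 (2.36) higher and Cdh1 (1.24, adjusted p = 0.0623) not called. Of 27 network genes, 10 were higher, 0 lower and 17 not called (median 0.56, adjusted p = 3.66e-12), with Dnmt3l (2.48, at least 2.26-fold), Zfp42 (2.16, at least 1.33-fold), Zfp296 (2.16) and Gdf3 (1.70) higher. The later genes gave 5 higher, 0 lower and 3 not called (median 1.81, adjusted p = 3.17e-09) and the earlier 4 higher, 0 lower and 5 not called (median 0.91, adjusted p = 3.17e-09). Fibroblast genes gave 0 higher, 8 lower and 20 not called (median -0.46, adjusted p = 4.58e-08), Acta2 (-2.48, 5.56-fold) and Vim (-1.79 ± 0.30, 3.45-fold, adjusted p = 0.000592) being lower and Col1a1 (-0.70, adjusted p = 0.251) not called. Trophoblast genes gave 3 higher, 0 lower and 5 not called (median 0.53, adjusted p = 0.00197), with Phlda2 (1.70) higher. Glycolysis gave 2 higher, 0 lower and 16 not called (3 higher and 0 lower adjusted over the list alone, adjusted p = 0.0244, and adjusted p = 0.113 with an estimated correlation). Germline genes gave 3 higher, 0 lower and 8 not called (median -0.07, mean 0.31 and test direction up, adjusted p = 0.367). The imprinted Igf2 (1.87, 3.65-fold) and the BMP response gene Id1 (1.87) rose, and the mesoderm gene Isl1 (-2.22, at least 3.84-fold) fell. In all 408 genes were called, 274 higher and 134 lower. With median scaling these were 334 and 72, and the all-gene median moved from -0.06 to 0.12.

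Across 0, 10, 30 and 100 nM, a trend over dose ranks tested for a linear slope, in log2 per dose step. Ly6g6c (1.87 ± 0.09, adjusted p = 1.32e-10), Krt17 (1.69 ± 0.09), Dppa5a (1.58 ± 0.08) and Esrrb (1.40 ± 0.07) had the largest positive slopes with Nccrp1 (1.51), Nppb (1.42), Aldh3a1 (1.39) and Dppa4 (1.37). Slopes were also positive for Pou5f1 (0.69 ± 0.08, adjusted p = 1.24e-05), Dnmt3l (0.73) and Zfp42 (0.66). Steps could be uneven: Krt17 averaged 8.47, 13.26, 13.50 and 14.02 at the 4 doses, Dnmt3l 7.82, 8.40, 8.29 and 10.29, and Zfp42 7.36, 7.95, 8.06 and 9.52, the last 2 above background at 100 nM only. No slope passed for Nanog (0.17, adjusted p = 0.266, though higher at 10 nM), Klf4 (0.10, adjusted p = 0.559) and Sox2 (-0.06, adjusted p = 0.751). Slc7a8 (-1.27 ± 0.09), Hoxb7 (-1.19), Hoxc6 (-1.15), Nfix (-1.06), Serpinf1 (-0.93), Lpl (-0.92), Acta2 (-0.89) and Hoxa5 (-0.88) had the largest negative slopes.

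For slopes the epidermal list gave 8 higher, 0 lower and 3 not called (median 0.79, adjusted p = 1.46e-13), with Krt14 (1.26) positive, while Krt6b (-0.16, adjusted p = 0.233) and Krt10 (0.00, adjusted p = 0.994), named after their values were seen, were not called. The epithelial list gave 11 higher, 0 lower and 8 not called (median 0.40, 12 higher and 0 lower adjusted over the list alone, adjusted p = 7.66e-13), with Krt19 (1.11), Cldn4 (0.87) and Krt8 (0.77) positive. The network had 10 higher, 0 lower and 17 not called (median 0.16, adjusted p = 3.09e-10), later genes 5 higher, 0 lower and 3 not called (median 0.61, adjusted p = 2.5e-08) and earlier genes 4 higher, 0 lower and 5 not called (median 0.27, adjusted p = 6.72e-08). Fibroblast genes gave 0 higher, 9 lower and 19 not called (median -0.19, adjusted p = 2.04e-09), with Vim (-0.69) and Lox (-0.57) negative. Trophoblast genes gave 4 higher, 0 lower and 4 not called (median 0.20, adjusted p = 0.00201). Antigen presentation gave 0 higher, 0 lower and 7 not called (adjusted p = 0.0454, and 0.395 with an estimated correlation). The trend called 449 genes, 292 with positive and 157 with negative slopes, and with median scaling 366 and 103.

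Cells kept at 0 nM were compared between days 79 and 22 to see whether the state without ligand held. Nkx2-3 (3.79 ± 0.32, at least 5.35-fold, adjusted p = 4.22e-07), a homeobox factor, Gdf3 (3.16 ± 0.22, 8.94-fold, adjusted p = 3.11e-08) and Igf2 (3.01 ± 0.20, 8.05-fold) were among the largest rises, with Adssl1 (3.46, at least 5.39-fold), Nuak1 (3.24, at least 5.74-fold), Gstp2 (2.97, at least 3.86-fold), Cdkn1c (2.96, 7.76-fold) and Cep19 (2.86, 7.26-fold). Dppa4 (2.20, at least 1.55-fold), Fbxo15 (2.02 ± 0.37, 4.04-fold, adjusted p = 0.00223) and Nanog rose. Esrp1 (-4.82 ± 0.29, at least 8.95-fold, adjusted p = 1.05e-08) was the largest fall, with Prl2c3 (-4.04, 16.4-fold), Prl2c4 (-3.44, at least 8.7-fold), Hoxb7 (-3.76, at least 2.73-fold), Hoxc6 (-3.29, at least 3.74-fold), Cldn6 (-3.21, at least 5.76-fold), Slc7a8 (-2.95, at least 2.89-fold) and Slitrk5 (-2.82, at least 3.16-fold). Prl2c3 and Prl2c4 are close relatives, and their probes were not checked against each other's sequence. Pou5f1 (-2.70 ± 0.26, 6.48-fold, adjusted p = 2.15e-06) fell too.

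Epithelial genes between the days gave 0 higher, 4 lower and 15 not called (median -0.27, 0 higher and 5 lower adjusted over the list alone, adjusted p = 6.74e-05), with Cldn4 (-2.38, at least 2.47-fold) lower, and earlier pluripotency genes 3 higher, 0 lower and 6 not called (median 0.63, adjusted p = 0.000562). Glycolysis gave 1 higher, 0 lower and 17 not called (2 higher and 0 lower adjusted over the list alone, adjusted p = 0.00252, and adjusted p = 0.0636 with an estimated correlation) and p53 targets 0 higher, 1 lower and 14 not called (adjusted p = 0.0412, and adjusted p = 0.0807 with an estimated correlation). Formative genes gave 1 higher, 2 lower and 3 not called (adjusted p = 0.0427, and adjusted p = 0.0946 with an estimated correlation), with Dnmt3b (-2.23, 4.7-fold) lower and Car14 (1.67) higher. Fibroblast genes gave 2 higher, 3 lower and 23 not called (adjusted p = 0.126), with Acta2 (-2.54, 5.82-fold) and Tnc (-1.43) lower and Mmp2 (1.28) higher. The network gave 4 higher, 1 lower and 22 not called (median -0.11, mean 0.19 and test direction up, adjusted p = 0.421). Of the cell cycle genes Tyms (-1.96) fell and Ccnd3 (1.13) rose. Esrrb (-0.18, adjusted p = 0.88), Dppa5a (-0.75, adjusted p = 0.13), Sox2 (-0.53, adjusted p = 0.383), Cdh1 (-1.16, adjusted p = 0.108) and Vim (0.49, adjusted p = 0.557) were not called. The test called 284 genes, 177 higher and 107 lower, and a fit of these groups alone called 102.

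Moving cells from 0 to 100 nM at day 25 and sampling at day 79, against 0 nM throughout, asked whether held cells still answered to the ligand. Dppa5a (6.89 ± 0.26, at least 77.2-fold, adjusted p = 4.36e-12), Esrrb (5.19 ± 0.22, at least 21.2-fold, adjusted p = 6.65e-12), Krt17 (5.16 ± 0.28, at least 32.6-fold) and Pou5f1 (4.93 ± 0.26, 30.5-fold, adjusted p = 2.38e-10) were among the largest rises, with Ly6g6c (5.16, at least 11.8-fold), Esrp1 (5.05, at least 10.5-fold), Dnmt3l (4.97, at least 13.2-fold) and Nccrp1 (4.57, 23.7-fold). Cldn6 (4.19, at least 11.4-fold), Dppa4 (3.81, 14-fold), Utf1 (2.97, at least 3.91-fold) and Zfp42 (2.14, at least 2.48-fold) rose, while Nanog (-0.01, adjusted p = 0.99), Fbxo15 (0.15, adjusted p = 0.919) and Sox2 (0.72, adjusted p = 0.163) were not called. Nkx2-3 (-3.68 ± 0.32, at least 6.26-fold), Akr1c18 (-3.51, at least 5.8-fold), Creb5 (-3.36, at least 4.65-fold), Car14 (-3.33, at least 2.17-fold), Lpl (-3.03, 8.17-fold), Adssl1 (-2.79, at least 6.3-fold), Diras2 (-2.78, at least 3.58-fold) and Col4a2 (-2.66, 6.33-fold) were the largest falls.

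Later pluripotency genes in the moved cells gave 5 higher, 0 lower and 3 not called (median 2.77, adjusted p = 2.61e-16), and the network 9 higher, 0 lower and 18 not called (median 0.41, adjusted p = 1.05e-14). The epidermal list had 7 higher, 0 lower and 4 not called (median 1.63, adjusted p = 2.59e-15), with Krt14 (3.96, at least 3.07-fold), Krtdap (2.40) and Klk10 (2.26) higher. The epithelial list had 10 higher, 0 lower and 9 not called (median 1.45, adjusted p = 5.36e-15), with Cldn4 (4.04, at least 7.82-fold) and Krt8 (2.67, at least 3.41-fold) higher. Earlier genes gave 3 higher, 0 lower and 6 not called (adjusted p = 0.0106, and 0.08 with an estimated correlation). Immediate early genes gave 2 higher, 0 lower and 11 not called (adjusted p = 0.041, and 0.13 with an estimated correlation). Of the formative genes, Dnmt3b (1.87) rose and Car14 (-3.33, at least 2.17-fold) fell. Germline genes gave 4 higher, 0 lower and 7 not called (median -0.12, mean 0.48 and test direction up, adjusted p = 0.0759), with Tdrd12 (2.74) higher. The imprinted Cdkn1c (-2.07, 4.2-fold) fell and Bmp4 (2.00) of the mesoderm list rose. Of the fibroblast genes, Thy1 (0.94, adjusted p = 0.149) and Zeb1 (-0.95, adjusted p = 0.0939) were not called. In all 305 genes were called, 234 higher and 71 lower.

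The early (100 against 0 nM, day 22) and late responses (0 to 100 against 0 nM, day 79) share no arrays. Addition time, exposure length and sampling day changed together and cannot be separated. Of 274 genes higher early and 234 late, 143 were higher in both, against 8.33 if independent. Of 134 lower early and 71 late, 27 were lower in both, against 1.24. Calls were opposite for 1 gene higher early and 4 higher late. Of the 538 genes called in either, 84.2% changed the same way. Across all genes, which are not independent replicates, r was 0.578.

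In the test of the difference itself, late minus early, Pou5f1 (2.88 ± 0.37, adjusted p = 0.000173), Cldn6 (2.51) and Dnmt3l (2.50 ± 0.29, adjusted p = 6.04e-05) rose more in the late response. Prl2c3 (4.56 ± 0.42, adjusted p = 5.33e-06), Slc7a8 (3.98 ± 0.38, adjusted p = 7.74e-06), Esrp1 (3.77 ± 0.41, adjusted p = 2.96e-05), Hoxc6 (3.45), Hoxb7 (3.21), Serpinf1 (3.40), Acta2 (3.37) and Prl2c4 (3.82) had the largest positive differences. Nkx2-3 (-4.01 ± 0.45, adjusted p = 4.49e-05), Creb5 (-3.06), Igf2 (-2.87), Gstp2 (-2.87), Nppb (-2.80) and Gdf3 (-2.64) were among the largest negative ones. Esrrb (0.57, adjusted p = 0.719), Krt8 (0.52, adjusted p = 1), Nanog (-0.77, adjusted p = 0.565) and Dppa4 (-0.56, adjusted p = 0.683) did not differ past the threshold. By list, fibroblast genes gave 4 higher, 0 lower and 24 not called (median 0.41, adjusted p = 5.68e-06), with Tnc (2.03) positive, and glycolysis 0 higher, 0 lower and 18 not called (median -0.61, adjusted p = 3.89e-05). Later pluripotency genes gave 2 higher, 0 lower and 6 not called (median 0.45, 3 higher and 0 lower adjusted over the list alone, adjusted p = 0.000313) and formative genes 2 higher, 1 lower and 3 not called (median 0.39, adjusted p = 0.0111). Interferon genes gave 1 higher, 0 lower and 17 not called (2 higher and 0 lower adjusted over the list alone, adjusted p = 0.0269, and adjusted p = 0.138 with an estimated correlation). Earlier pluripotency genes gave 0 higher, 1 lower and 8 not called (adjusted p = 0.029, and 0.125 with an estimated correlation). P53 targets gave 0 higher, 0 lower and 15 not called (adjusted p = 0.049, and 0.107 with an estimated correlation). The mesoderm gene Isl1 (2.11) was positive and the imprinted Cdkn1c (-1.73) negative. Limma called 100 genes, 60 positive and 40 negative, of which 87 were also called early or late. The count was 57 without replicate 1 of 100 nM day 22, 53 without replicate 1 of 0 nM day 79, and 60 and 54 without replicate 1 or 2 of the moved cells. Median scaling moved the all-gene median from 0.01 to -0.13.

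Cells at 100 nM and day 22 were set against the iPSC clone to see what still separated them. Ly6g6c (6.05 ± 0.30, at least 40.9-fold, adjusted p = 8.54e-11), Nccrp1 (5.04 ± 0.28, at least 27.6-fold), Krt17 (5.0 ± 0.28, 31.9-fold), Aldh3a1 (4.60, at least 16.7-fold), Nppb (4.31, 19.9-fold), Rasgrp1 (4.17, at least 8.28-fold), Hs3st3a1 (4.14, at least 6.54-fold) and Apcdd1 (4.12, at least 12.1-fold) were the largest excesses. Sox2 (3.13 ± 0.26, 8.75-fold, adjusted p = 1.02e-07) was higher on a probe that lay above the iPSC level in every infected group, and the cell cycle inhibitor Cdkn1a (1.69 ± 0.21, 3.23-fold, adjusted p = 8.71e-06) was higher. Fabp3 (-5.08 ± 0.24, at least 27.1-fold), Dnmt3l (-5.04 ± 0.21, 32.9-fold, adjusted p = 1.56e-11), Pla2g1b (-4.70, at least 11.6-fold), Sgk1 (-4.38, 20.8-fold), Cyp4f14 (-4.34, at least 6.48-fold), Aard (-4.13, at least 9.16-fold), Amn (-4.01, 16.1-fold) and Klf2 (-3.90, at least 5.07-fold) were the largest deficits. Nanog (-2.16 ± 0.25, 4.47-fold, adjusted p = 5.23e-06) was lower than in iPSC and Pou5f1 (0.07, adjusted p = 0.989) was not called.

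Of 27 network genes at 100 nM, 1 was higher, 16 lower and 10 not called (median -1.32, adjusted p = 6.77e-18), with Klf5 (-3.31, 9.89-fold), Dppa4 (-2.62, 6.16-fold), Zfp42 (-2.31, 4.97-fold), Dppa3 (-2.71, at least 2.92-fold), Esrrb (-1.85, 3.61-fold) and Dppa5a (-1.79, at least 3.46-fold) lower. Later genes had 0 higher, 7 lower and 1 not called (median -1.59, adjusted p = 2.92e-13) and earlier genes 0 higher, 5 lower and 4 not called (median -1.31, adjusted p = 1.48e-09), with Fbxo15 (-1.91) lower. Epidermal genes gave 9 higher, 0 lower and 2 not called (median 2.50, adjusted p = 3.58e-17), with Krt14 (3.88, at least 6.37-fold) and Krtdap (3.67) higher. Epithelial genes gave 7 higher, 0 lower and 12 not called (median 0.58, 8 higher and 0 lower adjusted over the list alone, adjusted p = 8.26e-07), with Krt19 (2.86), Rab25 (2.67) and Esrp1 (1.81) higher and Cdh1 (0.30, adjusted p = 0.892) not called. Endoderm genes gave 0 higher, 5 lower and 4 not called (median -2.83, adjusted p = 2e-11), with Sox7 (-3.44), Lama1 (-3.11) and Apoe (-2.98) lower. Muscle and adipose genes gave 0 higher, 3 lower and 5 not called (adjusted p = 0.00257, and adjusted p = 0.0569 with an estimated correlation), with Mylpf (-3.0) lower. Germline genes gave 0 higher, 3 lower and 8 not called (adjusted p = 0.00368, and 0.0768 with an estimated correlation). Endothelial genes gave 0 higher, 2 lower and 6 not called (adjusted p = 0.0257, and 0.107 with an estimated correlation). Fibroblast genes gave 0 higher, 3 lower and 25 not called (adjusted p = 0.0523), with Acta2 (-2.60) lower and Vim (0.06, adjusted p = 0.99) not called. Of 4 neural genes the counts were 1 higher, 0 lower and 3 not called (3 and 0 adjusted over the list alone), with Map2 (2.18) higher. The mesoderm gene Bmp4 (-3.64, 12.5-fold) and the stress gene Chac1 (-3.51) were lower. In all 560 genes differed, 279 higher and 281 lower.

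The cells moved to 100 nM were set against the same clone. Nccrp1 (5.03 ± 0.28, at least 27.5-fold, adjusted p = 8.36e-10), Krt17 (5.0 ± 0.28, 31.9-fold, adjusted p = 8.36e-10), Npy (4.57, at least 18.6-fold), Apcdd1 (4.46, at least 15.2-fold), Ly6g6c (4.35, at least 12.6-fold), Nppb (4.15, 17.7-fold), Cldn11 (3.76, at least 4.55-fold) and Hs3st3a1 (3.72, at least 4.89-fold) were the largest excesses, and Sox2 (3.47 ± 0.26, 11-fold) and Cdkn1a (1.86 ± 0.21, 3.63-fold, adjusted p = 3.61e-06) were higher. Pla2g1b (-4.77 ± 0.29, at least 11.8-fold), Cyp4f14 (-4.48, at least 6.62-fold), Sgk1 (-4.11, 17.3-fold), Amn (-3.77, 13.6-fold), Car4 (-3.76, at least 3.77-fold), Fabp3 (-3.63, 12.3-fold), Klf5 (-3.61, 12.2-fold) and Upp1 (-3.52, 11.5-fold) were the largest deficits. Dnmt3l (-2.62 ± 0.21, 6.15-fold, adjusted p = 6.11e-08) and Nanog (-1.91 ± 0.25, 3.76-fold, adjusted p = 2.78e-05) were lower. Pou5f1 (0.25, adjusted p = 0.814), Dppa5a (-0.78, adjusted p = 0.0707), Dppa4 (-0.98, under 2-fold, adjusted p = 0.00261) and Cdh1 (-0.12, adjusted p = 0.999) were not called.

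The network in the moved cells gave 1 higher, 11 lower and 15 not called (median -0.91, adjusted p = 8.32e-13), with Klf2 (-3.45, at least 5.18-fold), Dppa3 (-2.36), Zfp42 (-1.53) and Esrrb (-1.46) lower, later genes 0 higher, 4 lower and 4 not called (median -1.09, adjusted p = 1.18e-08) and earlier genes 0 higher, 5 lower and 4 not called (median -1.11, adjusted p = 5.26e-07). Epidermal genes gave 8 higher, 0 lower and 3 not called (median 1.79, adjusted p = 2.6e-13), with Krtdap (3.17) and Krt14 (2.92) higher. Endoderm genes gave 0 higher, 5 lower and 4 not called (median -1.57, adjusted p = 1.15e-10), with Sox7 (-3.45, at least 3.3-fold) lower. Germline genes gave 0 higher, 4 lower and 7 not called (adjusted p = 0.0106, and 0.114 with an estimated correlation). DNA methylation genes gave 0 higher, 2 lower and 11 not called (adjusted p = 0.025, and 0.0684 with an estimated correlation). Epithelial genes gave 3 higher, 0 lower and 16 not called (median -0.05, mean 0.28 and test direction up, 4 higher and 0 lower adjusted over the list alone, adjusted p = 0.2). Of 4 neural genes the counts were 3 higher, 0 lower and 1 not called, with Map2 (2.01) and Stmn2 (1.79) higher, and Id1 (1.95) of the BMP responses was higher. The total was 514 genes, 303 higher and 211 lower.

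**Figure D2:**
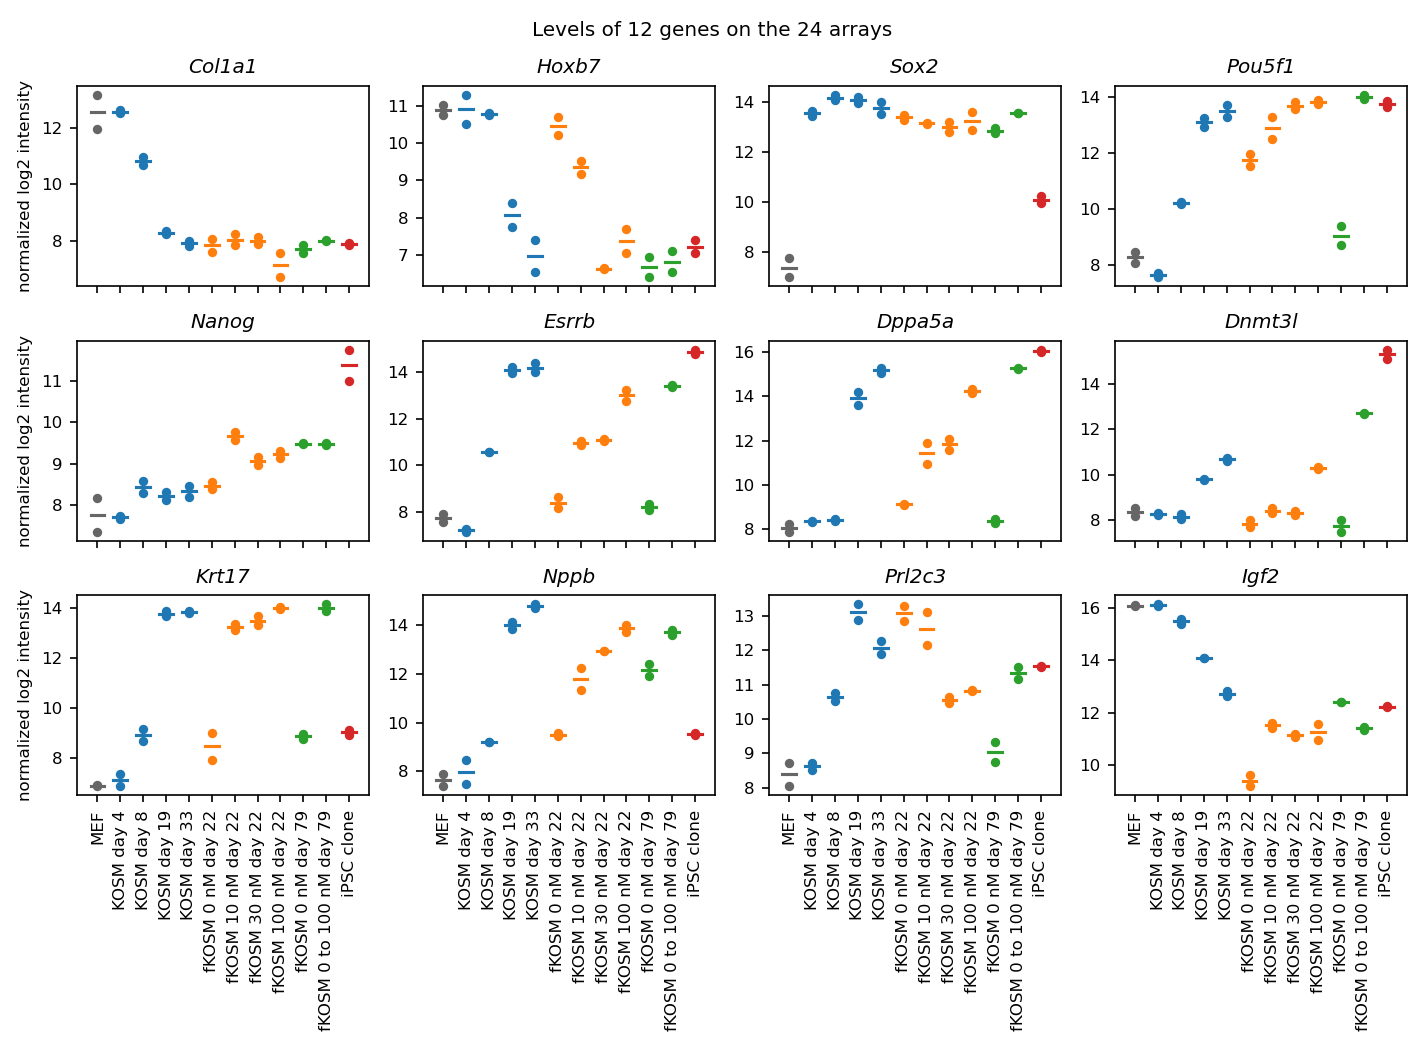
Normalized log2 intensity of 12 genes on the 24 arrays, with dots for arrays and short lines for group means. Pou5f1 averaged 8.28 in MEF, 11.75 with 0 nM Shield1 at day 22, 13.8 with 100 nM, 9.05 with 0 nM at day 79, 13.99 after the move to 100 nM and 13.73 in iPSC.

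Across all groups, the reported Sox2 probe averaged 7.40 in MEF, 10.11 in iPSC and between 12.85 (0 nM, day 79) and 14.17 (KOSM day 8) in the 10 infected groups. A second Sox2 probe stayed between 9.49 and 9.92 in all groups. Pou5f1 averaged 7.65 at KOSM day 4, 10.2 at day 8, 13.09 at day 19 and 13.49 at day 33, and its other probe 7.58, 8.47, 11.62 and 11.29 on these days. Klf4 on its reported probe lay between 8.34 and 9.47. Its second probe averaged 10.03 in MEF and 10.56 in iPSC, against 7.70 at 0 nM and 7.80 at 100 nM, day 22. Myc, Tdgf1 and Ifit1 lay above background on 0 arrays and were not tested, and the probes carried no named entry for Epcam, Snai2 or Meg3. The sex-linked list had 1 measured member, which was called in 0 of the 15 comparisons. Genes were reported from their brightest probe, and other probes often moved less. Of called genes with several probes, every other probe changed less than 2-fold for 65 of 103 at KOSM day 4, 164 of 328 at day 8, 151 of 358 at day 19, 166 of 360 at day 33, 151 of 406 in iPSC, 21 of 28 at 10 nM, 43 of 80 at 30 nM and 37 of 75 at 100 nM. Another probe had the opposite sign at p under 0.05 for at most 4 of these genes in a comparison.

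**Figure D3:**
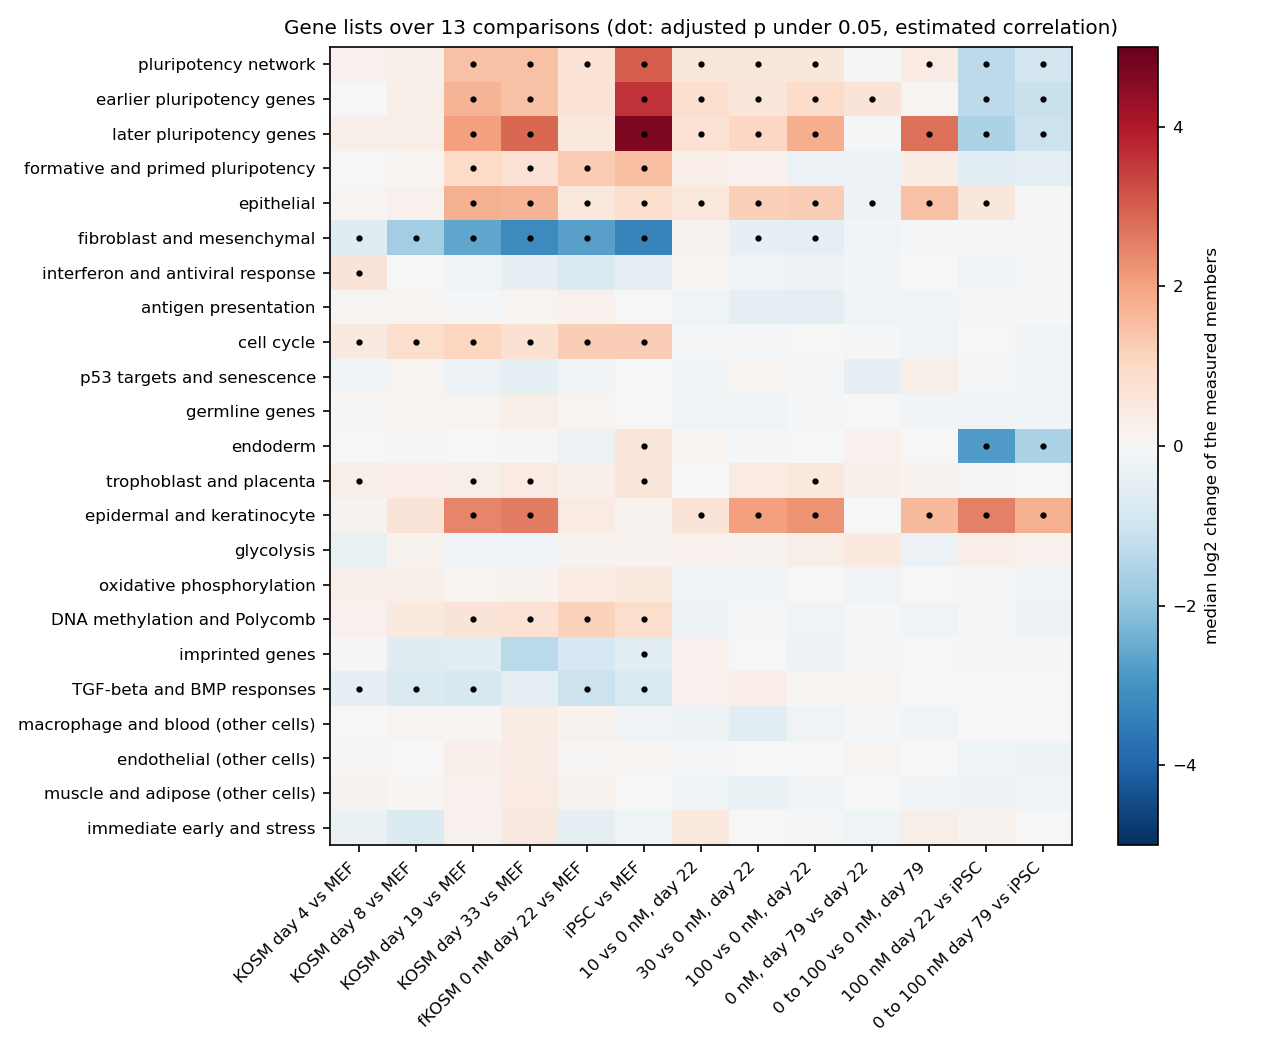
Median log2 change of the measured members of 23 gene lists (vertical) in 13 comparisons (horizontal), as colour, with a dot where camera gave an adjusted p under 0.05 with an estimated correlation. Medians ran from -3.28 for fibroblast genes to 4.67 for later pluripotency genes, both in iPSC against MEF.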

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

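The contrast of early and late responses, its gene lists and the fits without 1 array were planned, whereas the use of 1 such fit to judge an array and the split by replicate number were chosen after the results were seen. The early response to 100 nM Shield1 (day 22) and the late one (added at day 25, day 79) differed for 100 genes by the test of the difference itself. In log2, late minus early, with the early and late responses in brackets, the largest differences were Prl2c3 4.56 (-2.26, 2.3), Slc7a8 3.98 (-3.73, 0.26), Prl2c4 3.82 (-1.86, 1.96), Esrp1 3.77 (1.28, 5.05), Hoxc6 3.45 (-3.12, 0.33), Serpinf1 3.4 (-2.41, 0.99), Acta2 3.37 (-2.48, 0.9) and Hoxb7 3.21 (-3.07, 0.14). On the other side were Nkx2-3 -4.01 (0.34, -3.68), Creb5 -3.06 (-0.3, -3.36), Igf2 -2.87 (1.87, -1.01), Gstp2 -2.87 (1.98, -0.88), Nppb -2.8 (4.34, 1.54), Adssl1 -2.71 (-0.08, -2.79), Gdf3 -2.64 (1.7, -0.93) and Nuak1 -2.49 (0.86, -1.64). The Adssl1 call was lost without replicate 1 of 100 nM, day 22 (-2.41, adjusted p = 0.0618) or of 0 nM, day 79 (-2.29, adjusted p = 0.0633). The Nuak1 call was lost without the same arrays (-2.25 and -2.3, adjusted p = 0.0832 and 0.0674), replicate 2 of 0 nM, day 22 (-2.2, adjusted p = 0.0713) or replicate 2 of the moved cells (-2.2, adjusted p = 0.0947). Every other named difference held in each such fit. By list, the median difference was 0.41 for fibroblast genes, -0.61 for glycolysis, 0.45 for later pluripotency genes and 0.39 for formative genes. It was 0.19 for interferon genes, -0.67 for earlier pluripotency genes and 0.39 for p53 targets. Their adjusted p was 0.0269, 0.029 and 0.049, and 0.138, 0.125 and 0.107 with an estimated correlation.

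One of the 0 nM arrays at day 22 had the second largest background spread, but without it 63 of the 100 genes stayed called, which argues against that array as the whole source. A candidate explanation is that cells held at 0 nM drifted between days 22 and 79, so that the baseline moved. To keep the choice of genes apart from their measurement, the 100 genes of largest difference on the arrays of 1 replicate number were measured on the arrays of the other. The change at 0 nM made up more of the difference than the change between the 100 nM groups for 80 genes picked on replicate 1 and for 78 picked on replicate 2. Its median part was 1.49 and 1.33 log2, against 0.10 and 0.28 for the 100 nM groups. Whether this change at 0 nM was biological or a difference in culture stays open, as the labels give no batch to separate these.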

How the results depend on the processing

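The alternatives chosen after seeing the data are named with the methods. Unless stated, the cause of a shift was not tested. Of 195 counts under alternatives 185 stayed within 1.5 times the reported count, and 61 of 68 with 1 array left out. No list or named gene with a call reversed. Of 2415 list tests 2318 kept their side of the threshold, 49 lost it and 48 gained it, and of 4681 tests of named genes 4521 stayed called and 160 did not. With no minimum fold, which by construction adds genes, counts were 730 at day 4, 2145 at day 8, 725 at 30 nM, 786 for the moved cells against iPSC and 693 for the trend. Fits of the compared groups alone, with fewer degrees of freedom, called 3 genes at 10 nM, 102 between days at 0 nM and 62 for early against late. Without the 2 dimmest arrays 10 nM gave 107, and median scaling gave 52 for early against late. Leaving out 1 array, where the lone sample is assumed to vary like the other groups, gave 292 to 467 genes at day 4, 1271 to 1410 at day 8, 1585 to 1653 at day 19, 1655 to 1970 at day 33, 1783 to 1944 for iPSC and 1491 to 1581 for 0 nM against MEF, 90 to 201 at 10 nM, 324 to 451 at 30 nM, 322 to 384 at 100 nM, 198 to 268 between days at 0 nM, 217 to 277 for the moved cells, 441 to 496 and 390 to 452 for the early and late 100 nM cells against iPSC, 391 to 466 for the trend and 53 to 83 for early against late. Of 70 positions under alternatives 48 moved by less than the spread between replicates, and 43 of 60 with 1 array left out. With the floor of 50, positions in percent were 74.5 (day 19), 77.4 (day 33), 81.8 (100 nM), 77.2 (30 nM), 68.8 (10 nM), 65 (0 nM, day 22) and 79.4 (moved cells). With cyclic loess they were 23.9, 50.2, 74.6 and 78.1 at the KOSM days, 82.5, 77.2, 68.4 and 65.5 from 100 down to 0 nM, 66.5 at 0 nM, day 79, and 79.4 in the moved cells. Median scaling gave 74.8 (day 19), 76.2 (day 33), 64.2 (0 nM, day 22) and 66.7 (0 nM, day 79), and leaving out the 2 dimmest arrays 65.9 at 0 nM, day 22. With 1 array left out positions ran from 24.7 to 29.2, 51.1 to 54.2, 75.1 to 77.7 and 79 to 81.3 at the KOSM days, 82.2 to 85.4 at 100 nM, 76.6 to 79.8 at 30 nM, 68.5 to 72.9 at 10 nM, 65.8 to 70.4 at 0 nM, 66.8 to 71.3 at 0 nM, day 79, and 79.3 to 82.1 in the moved cells. The replicate numbers did not act as pairs of one kind over all groups. Correlations of replicate deviations between 66 pairs of groups ran from -0.37 to 0.64 (median 0.11, 34 over 0.1 and 17 under -0.1). On all KOSM days replicate 1 had the larger background spread (log2 ratios 0.79, 0.48, 0.71 and 1.42). The first axis of the deviations had the same sign on these days (0.35, 0.19, 0.31 and 0.62). It had the opposite sign in MEF, iPSC and every fKOSM group but 30 nM. A single block over all arrays cannot remove deviations of opposite sign. With replicate number as such a block the counts were 463, 1427, 1671, 1676, 1885, 1539, 186, 490, 417, 300, 315, 570, 533, 462 and 125, from day 4 against MEF to early against late. Not run were no background correction, since values at or under 0 have no log, a slide block, since no slide was given, and a filter at detection p under 0.01, replaced by the stricter multiple, while the deposited value table was already in use. Signal over background limits the dim genes: between 0 and 39 called genes per comparison lay above background on none of the arrays compared.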

Other observations

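The comparisons, the epidermal list and the fit without 1 array were planned, whereas their use to weigh explanations and the test of Sox2 against the clone were chosen after the results were seen. The Sox2 signal was high from day 4 in all 10 infected groups. Its lowest mean among them, fKOSM at 0 nM and day 79, exceeded the iPSC clone by 2.75 log2. A probe that reads vector transcript could give this excess. The clone is named for KOSM and may itself carry a vector, so it is no vector-free reference, and vector transcript and the cell's own Sox2 cannot be told apart. Whether the probe lies in the vector's coding insert was not tested, as no vector or probe sequence was at hand.

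Of 11 epidermal and keratinocyte genes, 8 rose with 100 nM Shield1, among them Krt17, Krt14 and Klk10, and 9 lay above the iPSC clone. Krt6b, by contrast, was called lower at 10 nM (-1.25) and was not called at 100 nM (-0.69). The list median at 100 nM was 2.27 without the dimmer 0 nM array, which argues against that array as the source. It exceeded that of iPSC by 2.5, which argues against a mere approach to the clone. Other explanations were not tested. KOSM cells, for which the labels give no Shield1 dose, had 9 members higher and 0 lower than MEF at days 19 and 33. The list medians were 2.43 and 2.58. The list could thus rise without the compound, which argues against Shield1 as a requirement. In fKOSM cells an effect of the compound itself, an effect of the regulated factor and outgrowth of a cell type in culture all stay open, and no group had Shield1 without fKOSM.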
